A study of Homo sapiens with 6 samples.

How the data were processed

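Poly(A)-selected, strand-marking RNA-seq libraries were made from 200 ng of RNA each from H9 cells, an established human embryonic stem cell line, grown in RSeT, a medium for naive-type human pluripotent cells. From 24 h after passage, the cells received 10 nM DZNep, an inhibitor of S-adenosylhomocysteine hydrolase, and 5 nM TSA (trichostatin A), a histone deacetylase inhibitor. Together with these they received 2.5 µM UNC1999, an inhibitor of the histone methyltransferases EZH2 and EZH1, or 2.5 µM UNC2400, its N-methylated analog of low activity, for 48 h. There were 3 libraries per compound and no arm without either compound. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

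The counts are whole numbers per gene name, deposited by the authors without normalization. Trim Galore 0.4.0, TopHat2 2.0.13, featureCounts and Subread 1.5.0 with build hg19 are named per the submitters' processing notes, which give no roles or order. The annotation version, the strand setting and the handling of reads with several matches are not given in the sources used here. The deposited count table is marked as having duplicates removed, without saying duplicates of what. It holds 53712 gene names. Of these, 26 were turned into calendar dates, as spreadsheet programs do, and 21 of the 26 were expressed enough to be tested; they stayed in the tests and are not named. The authors' deposited log2 values cover 20368 genes and are marked as normalized and batch-corrected. In them the median absolute offset of a replicate number from the gene mean was 0.001 to 0.00548. In log2 CPM from the counts it was 0.0454 to 0.0552, so differences between replicate numbers had been removed. The labels do not say whether the number marks a batch. The authors' deposited comparison table holds log2 fold changes, p-values and test scores under the column names limma uses, per the file headers; positive values mean higher in UNC1999, checked against the counts.

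Differential expression was tested on the counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, two-sided, TMM factors, group only). Low-count genes were removed with edgeR's default filter on group, which kept 17596 genes. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Log2 fold changes are UNC1999 minus UNC2400 and are given ± SE, and levels are TMM-scaled CPM given as mean ± SD over 3 libraries. Intervals of single genes are 95% intervals of the log2 fold change. Counting intervals of low genes are exact 95% intervals from summed counts, and a count of 0 allows up to 3 counts; both cover counting error only, since reads without molecular identifiers are not independent molecules.

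Before the data were examined, 27 gene lists were fixed: 8-cell-stage factors, DUX4 target families, naive, core and primed pluripotency, subunits of Polycomb repressive complex 2 (PRC2), HOX genes, developmental Polycomb targets, trophoblast, amnion, mesoderm and primitive streak, endoderm and hypoblast, neuroectoderm, fibroblast or feeder, germline, nucleolar ribosome biogenesis, cytosolic ribosomal proteins, p53 targets, integrated stress response, sterol and lipid synthesis, lysosome, G2/M phase, S phase, DNA methylation machinery, imprinted genes, mitochondrially encoded genes, and metallothionein and xenobiotic genes. Lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 25 such lists. Older gene symbols were matched through a table of gene names. Genes were named in the text by a rule fixed at the same time: EZH2, EZH1, EED and SUZ12; ZSCAN4, LEUTX, DUXA, DUX4, TPRX1, KLF17, POU5F1, NANOG, SOX2, DPPA3 and DPPA5 where tested; up to 8 genes in each direction with the largest fold among symbol-bearing genes past the threshold, with a mean log2 CPM of at least 1 and no overlap between groups; and up to 4 members of each list with the smallest p. ZSCAN4, LEUTX, DUXA, DUX4 and KLF17 were below the low-count filter and are given as counts, with KLF17 also as fitted without that filter. Some genes that the rule takes are not reported here.

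Library totals and shares were compared by exact two-sided permutation tests, for which 3 against 3 libraries cannot give a p below 0.1. Genomic span, exon length and GC content came from GENCODE release 29 by gene name, a build other than that of the counts, and were used as gene properties only; no coordinates are given. They were found for 84.4% of tested genes and 89.2% of the genes past the threshold. Exon length was the joined length of the exons of all transcripts of a gene, so it can exceed that of a mature transcript. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, other low-count filters, other thresholds, the replicate number as a block, the authors' log2 values, other list tests and leaving out libraries. Where alternatives are counted for a single gene, the other thresholds are left out. Per-library offsets that removed trends along span, exon length and GC (splines with 4 degrees of freedom) were chosen after seeing the data.

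The procedures were tested on simulated data for UNC1999 against UNC2400 over 17596 genes. Of 100 genes changed 1.5-fold, 65 were recovered, and of 100 changed 2-fold, 89. There were 8 calls among unchanged genes. Only 200 genes were changed, as many up as down, while 52.7% of genes passed in the data. These rates therefore check the procedure and do not give the recovery or false calls of this comparison. Replicates of a group differed by more than sampling noise, with a mean chi-square of 4.22 to 11.92 per gene at 1 degree of freedom. This argues against repeat sequencing of the same library, but does not show that replicates came from separate cultures. Every library was counted as a separate sample. Figures were drawn with matplotlib 3.10.9.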

Results

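The study set the PRC2 inhibitor UNC1999 against its analog UNC2400 in H9 cells that also received DZNep and TSA. Per its title it is about control of nucleolar organisation and of the 8-cell-like state by LINE1 and PRC2. There were 3 libraries per compound. Total counts were 29699441, 42345448 and 30633829 for UNC2400 replicates 1 to 3, and 34481593, 33720474 and 33522942 for UNC1999 replicates 1 to 3. A count of 0 therefore allows up to 0.0708 to 0.101 CPM per library. Total counts overlapped between the groups (exact two-sided permutation p = 1). This rests on UNC2400 replicate 2: the other UNC2400 libraries lay below all UNC1999 libraries, and without it p was 0.1 (exact), the smallest possible. The number of genes detected was 27572 ± 1590 (SD, n = 3) for UNC2400 and 27707 ± 1577 (SD, n = 3) for UNC1999 (exact p = 0.8). The 50 most abundant genes took 13.8% ± 0.855 and 14.9% ± 0.246 (SD, n = 3 each; exact p = 0.2), and mitochondrially encoded genes 5.46% ± 1.03 and 5.90% ± 0.31 (SD, n = 3 each; exact p = 0.5). The smallest p that 3 against 3 libraries allow is 0.1.

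UNC1999 and UNC2400 libraries differed in 52.7% of the genes tested by edgeR's quasi-likelihood test. TWIST1 and CER1 were among the genes that rose most, and CTNNA2, CDH13 and HMCN1 among those that fell most. Of 17596 genes tested, 4714 were higher and 4554 lower in UNC1999 at the same dose and time, 626 and 459 of them by more than 2-fold. Scaling held the median log2 shift of all genes near 0 (0.0163 with TMM, 0.0051 with RLE, 0.0307 with upper-quartile factors). Directions, those of small folds above all, are therefore relative to the bulk of genes. A shift shared by most genes would not be seen. The median absolute log2 fold change of the genes past the threshold was 0.42. All UNC1999 values lay above or below all UNC2400 values for 60.6% of genes, where chance gives 10%. The first principal component held 67.8% of the variance and parted the groups. UNC1999 replicate 1 lay at a score of 20.1 on it, the other UNC1999 libraries at 39.3 and 41.4, and the UNC2400 libraries between -35.2 and -31.6. Without UNC1999 replicate 1, 10080 genes passed. Of 25 fixed lists with enough members, 5 were called higher and 7 lower by camera, and 0 with an estimated correlation (lowest adjusted p = 0.463; 2 at an unadjusted p under 0.05).

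Among the genes that rose most, TWIST1, a transcription factor of mesoderm and neural crest, went from 0.752 ± 0.14 to 14.6 ± 4.15 CPM (SD, n = 3 each), a log2 fold change of 4.25 ± 0.23 (SE; adjusted p = 9.45e-10). CER1, a secreted antagonist of NODAL and BMP signals, went from 3.48 ± 0.299 to 54.7 ± 17.9 CPM (SD, n = 3 each), a log2 fold change of 3.97 ± 0.21. FAM167A rose by 3.21 ± 0.23, the phospholipid-binding protein gene ANXA1 by 2.97 ± 0.34, and the transcription factor genes KLF2 and CREB5 by 2.86 ± 0.21 and 2.71 ± 0.28 (log2, SE). S100A14 rose by 2.71 ± 0.21 and the small GTPase gene RHOB by 2.69 ± 0.14, RHOB from 32.7 ± 1.62 to 210 ± 56.1 CPM (SD, n = 3 each). Among the genes that fell most, the metallothionein pseudogene MT1JP fell by 2.26 ± 0.19, a value that is uncertain because near-identical copies exist. CTNNA2, an alpha-catenin gene, fell by 2.11 ± 0.17, the extracellular matrix gene HMCN1 by 2.04 ± 0.13, the cadherin gene CDH13 by 1.98 ± 0.16, and the scaffold gene MAGI2 by 1.97 ± 0.09. SLC25A21, COL20A1 and the tryptophan-degrading enzyme gene IDO1 fell by 1.98 ± 0.24, 1.89 ± 0.22 and 1.76 ± 0.11 (log2, SE; adjusted p from 3.50e-10 to 3.83e-06 for the genes that fell).

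**Figure D1:**
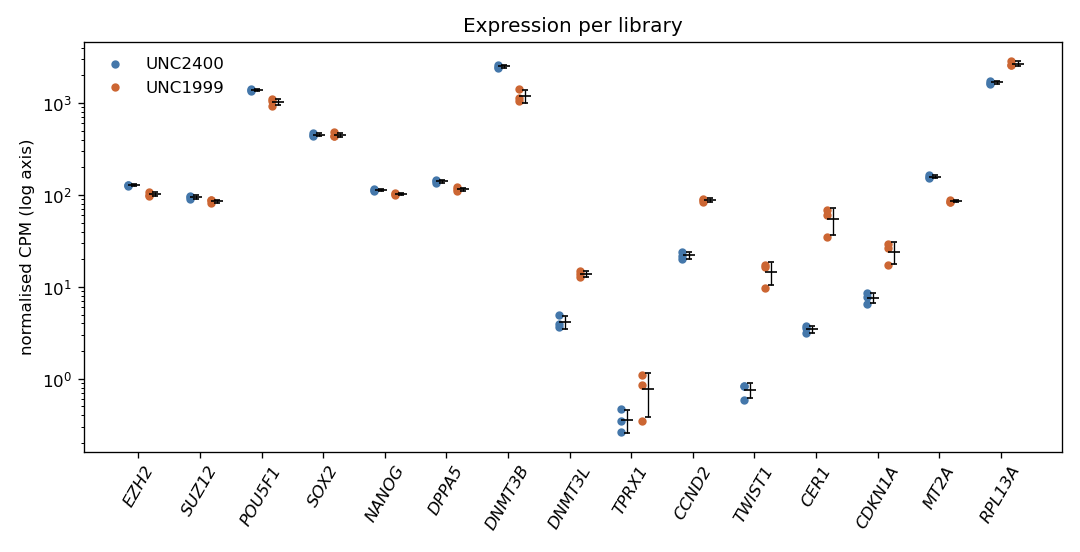
Normalised CPM (log axis) of 15 genes in each library. Points are libraries, dashes with bars are the mean and SD of 3. TWIST1, CER1 and CCND2 lie higher in all UNC1999 libraries, MT2A and DNMT3B lower, and SOX2 overlaps between the groups.

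EZH2, the catalytic subunit, went from 128 ± 2.46 to 102 ± 5.46 CPM (SD, n = 3 each), a log2 fold change of -0.33 ± 0.05 (SE; adjusted p = 5.46e-05). SUZ12 fell by 0.14 ± 0.05 (adjusted p = 0.0291), a call that 8 of the alternatives end. EZH1 had a log2 fold change of -0.12 with a 95% interval of -0.30 to 0.05, and EED one of 0.13 with an interval of -0.02 to 0.28. Without UNC1999 replicate 1, EED passed (0.18, adjusted p = 0.0146). Of 13 tested PRC2 subunits and cofactors, 2 rose and 6 fell, with the same counts adjusted over the list alone. The cofactor gene C17orf96 (EPOP) rose by 1.36 ± 0.13 and LCOR by 0.28 ± 0.07, while PHF19 fell by 0.61 ± 0.06 (log2, SE). The list as a whole was not called (camera adjusted p = 0.302), and its mean lay near 0 and its median at -0.12.

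Among developmental Polycomb targets, more genes rose than fell. Of 163 listed genes, 60 were expressed enough to test, of which 31 rose, 2 fell and 27 did not pass. Adjusted over the list alone, the counts were the same. In UNC2400 the listed genes had a median of 0.0764 CPM, and 28 of 163 reached 1 CPM. Genes near that median pass the low-count filter only where UNC1999 is higher, and have little room to fall. These counts and the median of tested members are therefore partly set by the filter. The cell cycle gene CCND2 rose from 22.0 ± 1.98 to 88.1 ± 3.56 CPM (SD, n = 3 each), a log2 fold change of 2.0 ± 0.06 (SE; adjusted p = 4.28e-12). SOX21 rose by 1.37 ± 0.05 (log2, SE). The list's median log2 fold change was 0.55 (camera adjusted p = 4.91e-05; adjusted p = 0.463 with an estimated correlation). HOX genes were mostly below the filter: 2 of 39 were tested, too few for a list test, and both were past the threshold as higher, also adjusted over the list alone. A gene as low in UNC2400 as HOXB2 passes the low-count filter only where UNC1999 is higher, so these counts say nothing of the direction of HOX genes in general. HOXB2 had 5 counts over the UNC2400 libraries and 69 over the UNC1999 libraries, and HOXB1 rose by 1.83 ± 0.35 (log2, SE).

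Several factors that mark the human 8-cell stage were at the limit of detection. DUX4, DUXA and LEUTX had 0 counts in all 6 libraries, so no fold can be given. The handling of reads with several matches is not given. Where near-identical copies exist, as for DUX4, a count of 0 therefore does not show absence. ZSCAN4 had 2 counts over the UNC2400 libraries and 5 over the UNC1999 libraries, a ratio of 2.52 with a counting interval of 0.413 to 26.5, which does not exclude equal levels. KLF17, a factor of naive and early embryonic cells, had 16 and 41 counts, a ratio of 2.59 with a counting interval of 1.42 to 4.94; with no low-count filter its log2 fold change was 1.30 (edgeR adjusted p = 0.0487). No gene of the DUX4 target families was tested, and none of the 42 in the table reached 1 CPM on average in UNC2400. Family members with near-identical copies share the limit on reads with several matches. Of 27 genes of the list of 8-cell-stage factors in the table, 5 reached 1 CPM in UNC2400. Of the 9 tested, 7 rose and none fell, also adjusted over the list alone, counts that the low-count filter partly sets (camera adjusted p = 0.0167, and 0.534 with an estimated correlation). Those that rose include the alkaline phosphatase gene ALPPL2 (1.44 ± 0.18, uncertain because of near-identical copies) and the cyclin gene CCNA1 (1.42 ± 0.20). ALPPL2 is also on the list of naive markers, so its rise does not mark the 8-cell stage alone. The zinc finger genes ZNF675 and ZNF280A rose by 0.30 ± 0.05 and 1.63 ± 0.30 (log2, SE). The homeobox gene TPRX1 went from 0.358 ± 0.101 to 0.77 ± 0.387 CPM (SD, n = 3 each; adjusted p = 0.028). Its call was lost in 10 alternatives, with DESeq2 among them (adjusted p = 0.0504), and without UNC1999 replicate 2 its log2 fold change went from 1.13 to 0.76 (adjusted p = 0.177).

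**Figure D2:**
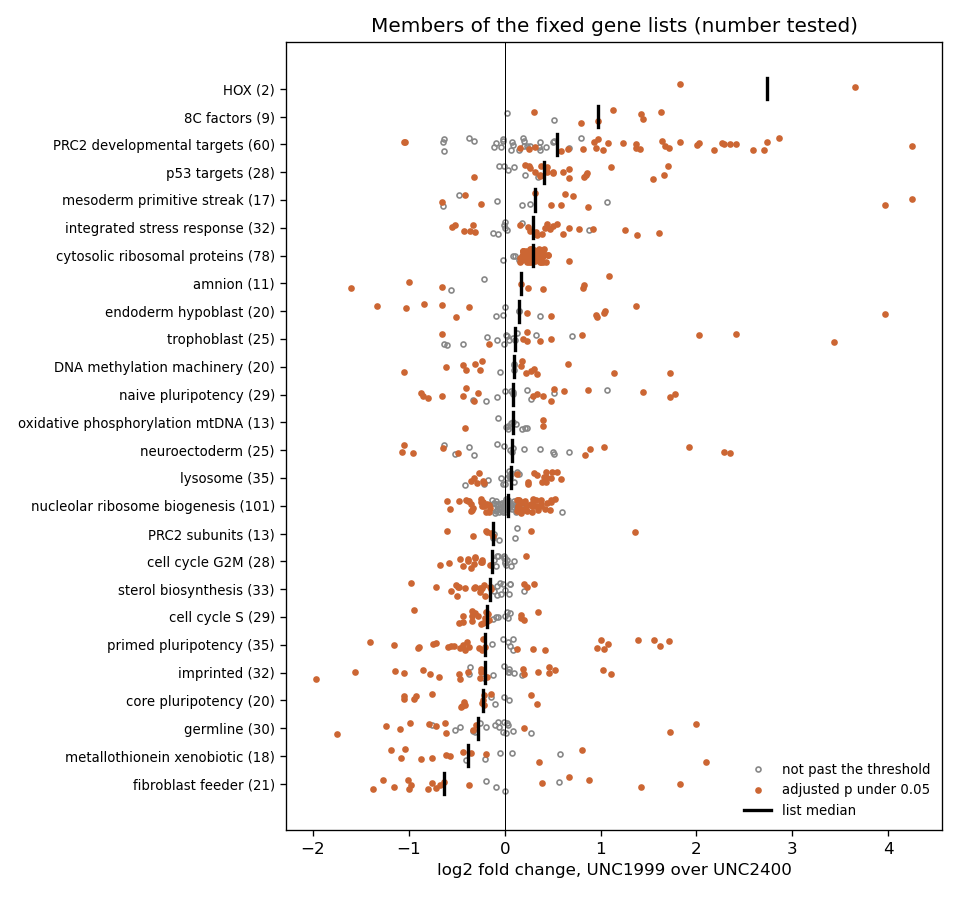
Log2 fold change (UNC1999 over UNC2400) of each tested member of the fixed gene lists, filled where the adjusted p was under 0.05; black bars are list medians and the number tested stands in brackets. Ribosomal protein genes lie in a narrow band around 0.29, and developmental Polycomb targets spread to the right around 0.55.

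Core pluripotency genes fell on balance: of 20 tested, 14 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 0.00109; adjusted p = 0.534 with an estimated correlation). POU5F1 went from 1393 ± 29.2 to 1024 ± 80.8 CPM (SD, n = 3 each), a log2 fold change of -0.44 ± 0.06 (SE). The de novo methyltransferase gene DNMT3B, the telomere-binding protein gene TERF1 and the non-coding RNA gene LINC-ROR fell by 1.06 ± 0.09, 0.94 ± 0.08 and 1.05 ± 0.07 (log2, SE). NANOG fell by 0.14 ± 0.05 (adjusted p = 0.0233, lost in 6 alternatives). SOX2 had a log2 fold change of -0.01 with a 95% interval of -0.13 to 0.11. Naive markers went both ways, with 10 of 29 higher and 8 lower, as adjusted over the list alone (camera adjusted p = 0.549). DNMT3L rose by 1.73 ± 0.12 and DPPA3 by 0.40 ± 0.12 (adjusted p = 0.0588 without UNC1999 replicate 3 and 0.303 with length and GC offsets), and DPPA5, NLRP2 and NLRP7 fell by 0.28 ± 0.05, 0.85 ± 0.07 and 0.80 ± 0.06 (log2, SE). Primed markers did too, with 11 of 35 higher and 18 lower, as adjusted over the list alone. Their median was -0.20 and their mean 0.02 (camera adjusted p = 0.379). NEFL, SALL1, ZIC2 and VIM rose by 1.39 ± 0.06, 1.71 ± 0.09, 1.55 ± 0.11 and 1.0 ± 0.08 (log2, SE).

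Lineage markers were mixed, and camera called no list of an embryonic or extraembryonic lineage with the low-count filter. The directional test fry does not compare a list with other genes. It called mesoderm and primitive streak (adjusted p = 0.000262), trophoblast (0.0151) and endoderm and hypoblast (0.0486) higher, and amnion lower (0.0144). In mesoderm and primitive streak, 8 of 17 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.155, and 0.00849 with no low-count filter); NODAL and its feedback inhibitor LEFTY2 rose by 0.87 ± 0.05 and 0.71 ± 0.06 (log2, SE). In endoderm and hypoblast, 8 of 20 rose and 6 fell, as adjusted over the list alone (camera adjusted p = 0.549); OTX2 and LBH rose by 0.96 ± 0.07 and 0.95 ± 0.07, and LAMA1 fell by 1.03 ± 0.09. In neuroectoderm, 6 of 25 rose and 5 fell, as adjusted over the list alone (camera adjusted p = 0.705); NES, STMN2 and SOX3 rose by 0.89 ± 0.05, 1.93 ± 0.14 and 1.03 ± 0.14, and DCX fell by 0.65 ± 0.07. In trophoblast, 9 of 25 rose and 2 fell, as adjusted over the list alone (camera adjusted p = 0.203). CCR7 and MSX2 were higher by 3.44 ± 0.45 and 2.41 ± 0.32 from under 0.3 CPM. Genes that low in UNC2400 pass the low-count filter only where UNC1999 is higher. Of 50 trophoblast genes in the table, 20 reached 1 CPM in UNC2400, so the filter partly sets this count. The other lineage lists may share this limit. In amnion, 6 of 11 rose and 3 fell, as adjusted over the list alone (camera adjusted p = 0.963), and BMP4 rose by 0.82 ± 0.09 while MUC16 fell by 1.60 ± 0.19. Fibroblast or feeder markers, mostly extracellular matrix genes that stem cells also express, fell in 12 of 21 and rose in 5, as adjusted over the list alone (camera adjusted p = 0.0229; adjusted p = 0.534 with an estimated correlation). With the length and GC offsets the list was no longer called (adjusted p = 0.0859), while its median went from -0.63 to -0.51, with 12 genes lower and 7 higher. FN1, COL6A2, COL6A1 and COL1A1 fell by 1.37 ± 0.08, 1.16 ± 0.07, 1.01 ± 0.08 and 0.76 ± 0.07 (log2, SE).

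Genes of cytosolic ribosomal proteins rose almost as one: 74 of 78 rose and none fell, also adjusted over the list alone, with a median of 0.29 (camera adjusted p = 4.56e-13; adjusted p = 0.534 with an estimated correlation). RPL13A rose by 0.67 ± 0.06, RPS13 by 0.44 ± 0.06 and RPS19 by 0.41 ± 0.06 (log2, SE). Counts of this family are uncertain because of its many processed pseudogenes. The family took 5.93% ± 0.276 of counts in UNC2400 and 7.62% ± 0.337 in UNC1999 (SD, n = 3 each; exact p = 0.1). These genes have short genomic spans, and with offsets for span, exon length and GC their median was 0.04 and the list was no longer called (adjusted p = 0.0888). Nucleolar ribosome biogenesis genes went both ways, with 37 of 101 higher and 20 lower, as adjusted over the list alone (camera adjusted p = 0.302). With the offsets 16 were higher and 30 lower, and the median went from 0.03 to -0.05. HEATR1 and TCOF1, factors of ribosomal RNA transcription, fell by 0.61 ± 0.06 and 0.57 ± 0.07, and NLE1 and POLR1D rose by 0.53 ± 0.06 and 0.42 ± 0.05 (log2, SE).

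Targets of p53 rose in 21 of 28 and fell in 1 (22 and 1 adjusted over the list alone; camera adjusted p = 3.04e-05; adjusted p = 0.534 with an estimated correlation). The cell cycle inhibitor gene CDKN1A went from 7.61 ± 0.97 to 24.2 ± 6.27 CPM (SD, n = 3 each), and PLK2, TNFRSF10B and PHLDA3 rose by 1.55 ± 0.15, 1.11 ± 0.10 and 0.82 ± 0.06 (log2, SE). Genes of the integrated stress response rose in 18 of 32 and fell in 6 (19 and 6 adjusted over the list alone; camera adjusted p = 0.0493; adjusted p = 0.618 with an estimated correlation), a call that ends with the length and GC offsets (adjusted p = 0.299) and without UNC2400 replicate 2 (0.0812), UNC2400 replicate 3 (0.0521) or UNC1999 replicate 3 (0.0558). Its phosphatase subunit gene PPP1R15A rose by 1.38 ± 0.12 and the amino acid transporter gene SLC3A2 by 0.92 ± 0.09. Cell cycle genes fell on balance. In the G2/M list 14 of 28 fell and 1 rose, as adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.686 with an estimated correlation), TOP2A by 0.68 ± 0.06 and MKI67 by 0.44 ± 0.06. In the S-phase list 16 of 29 fell and 4 rose (17 and 4 adjusted over the list alone; camera adjusted p = 0.0167; adjusted p = 0.686 with an estimated correlation), and POLA1 fell by 0.94 ± 0.08 while CDT1 rose by 0.35 ± 0.05.

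Sterol and lipid synthesis genes fell in 18 of 33 and rose in 3 (19 and 3 adjusted over the list alone; camera adjusted p = 0.0157; adjusted p = 0.725 with an estimated correlation), ACACA by 0.98 ± 0.10 and SREBF2 by 0.51 ± 0.07 (log2, SE). Without UNC1999 replicate 2 the list's adjusted p was 0.0647, and with fry it was 0.1. Metallothionein and xenobiotic genes fell in 10 of 18 and rose in 3, as adjusted over the list alone (camera adjusted p = 0.00759; adjusted p = 0.463 with an estimated correlation). The metal-binding genes MT1H, MT2A and MT1F fell by 1.04 ± 0.05, 0.88 ± 0.05 and 0.76 ± 0.05, values that are uncertain where near-identical family members share reads. Lysosomal genes rose in 14 of 35 and fell in 6 (14 and 8 adjusted over the list alone; camera adjusted p = 0.157), NEU1 by 0.55 ± 0.06. In the DNA methylation machinery 9 of 20 rose and 7 fell, as adjusted over the list alone (camera adjusted p = 0.549), and the maintenance methyltransferase gene DNMT1 fell by 0.61 ± 0.07. Germline genes fell in 10 of 30 and rose in 3 (9 and 3 adjusted over the list alone; camera adjusted p = 0.0365; adjusted p = 0.534 with an estimated correlation), DAZL by 1.24 ± 0.15 and TDRD12 by 0.79 ± 0.06. That list's adjusted p was 0.0586 without UNC2400 replicate 1, 0.0574 without UNC2400 replicate 3, 0.0844 without UNC1999 replicate 1 and 0.0559 without UNC1999 replicate 3. Imprinted genes fell in 14 of 32 and rose in 8, as adjusted over the list alone (camera adjusted p = 0.302); PHLDA2 rose by 1.11 ± 0.12 and SNURF, which overlaps another gene, fell by 1.15 ± 0.14. Of 13 mitochondrially encoded genes, 2 rose and 1 fell, as adjusted over the list alone (camera adjusted p = 0.539, and 0.00761 without UNC2400 replicate 1).

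Log2 fold changes also followed the genomic span of protein-coding genes. In the decile of genes with the shortest spans (median 3.56 kb) the median log2 fold change was 0.22, with 666 genes higher and 109 lower, and in the decile with the longest (median 292 kb) it was -0.41, with 85 higher and 865 lower. Across 13862 genes, which are not independent replicates, Spearman's rho was -0.41. Slopes against span were fitted to each library's deviation from the gene mean of all 6 libraries. They lay between -0.063 and -0.023 log2 per doubling in UNC1999 libraries and between 0.043 and 0.052 in UNC2400 libraries. Such deviations cancel out over the libraries, so the opposite signs follow from the centring, and only the difference between groups carries meaning.

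**Figure D3:**
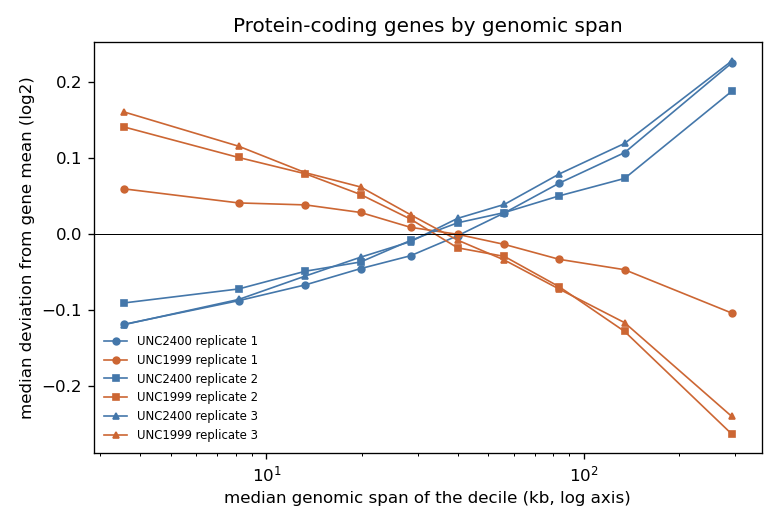
Median deviation from the gene mean (log2) in deciles of protein-coding genes by genomic span (kb, log axis), 1 line per library. Lines of UNC1999 libraries run downwards and those of UNC2400 libraries upwards. The gene mean is that of all 6 libraries, so only the difference between groups carries meaning. UNC1999 replicate 1 has the flattest of the UNC1999 lines.

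The authors' deposited table lists 20901 genes, of which 9196 have an adjusted p under 0.05, 4453 higher and 4743 lower in UNC1999. Among the 17596 genes in both analyses, 8768 were past the threshold in both, where independent lists would share 4700, and all 8768 had the same direction. Both analyses used the same 6 libraries, so a large overlap was bound to appear and is no independent support. The authors' deposited table had called 8924 of these genes and the count-based test 9268.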

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

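The length and GC offsets were chosen after seeing the data; a direction was read only where a value was past the threshold. The number of genes past the threshold, 9268, stayed within 1.5 times in every alternative run, from 6320 (without replicate 3 of both groups) to 11840 (adjusted p under 0.2). The genes higher in UNC1999 numbered 4714, and 3131 to 4925 when libraries were left out, the lowest without replicate 3 of both groups, where fewer libraries were tested. Members of fixed lists past the threshold numbered 481, and 418 to 511. Single genes were not followed at the thresholds of 0.2 and 0.01. In every other alternative run, 105 of 117 named genes kept their side of the threshold and direction. The rest changed side with no change of direction. The 12 list calls became 0 with an estimated correlation and 20 with fry, which asks whether a list moves and not whether it moves more than other genes. Fry ended the call of the sterol list (adjusted p = 0.1) and called the amnion list lower (adjusted p = 0.0144), which camera had not called in either direction (0.963); the cause was not tested. With the offsets, 7556 of 14845 genes with a length passed; of 8262 that had passed, 5946 kept their call and direction and 68 turned. With them 9 lists were called; those lost were ribosomal proteins (median 0.29 before, 0.04 after), stress response (0.30 and 0.09) and fibroblast markers, whose median stayed nearer its size (-0.63 and -0.51). The labels state no pairing, so the main fit had no replicate block. Same-numbered libraries deviated together weakly (correlations 0.0237, 0.0839 and 0.124), and 5 of 6 libraries correlated best with their own number. The authors' log2 values had the replicate number removed, so the numbers may mark a batch. With the replicate number as a block, edgeR called 9562 genes (4867 higher, 4695 lower), DESeq2 7185 (3363 higher, 3822 lower), limma on the authors' log2 values 9038 (4519 higher, 4519 lower); camera called 12 lists and 495 list members passed. Depth limits genes under about 1 CPM, among them most 8-cell-stage factors, DUX4 target families and HOX genes.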

Other observations

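In the UNC2400 libraries, the lists differed in level. Primed markers were at 1 CPM or more for 35 of 36 genes in the table, with a median of 58.8 CPM, and naive markers for 24 of 37, with a median of 6.79 CPM. Core pluripotency genes were all above 10 CPM, 20 of 20. No HOX gene of 39 reached 1 CPM, and 28 of 163 developmental Polycomb targets did.

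Of the gene groups not yet described, 2 were listed after their values had been seen, so their tests are not independent. Immediate early and AP-1 genes rose in 21 of 28 and none fell, as adjusted over the list alone (camera adjusted p = 2.19e-05; adjusted p = 0.494 with an estimated correlation). JUN, FOSL2 and ATF3 rose by 2.17 ± 0.11, 2.12 ± 0.20 and 1.61 ± 0.17 (log2, SE). Subunits of PRC1, the other main Polycomb complex, rose in 12 of 25 and fell in 4, as adjusted over the list alone (camera adjusted p = 0.0831; adjusted p = 0.494 with an estimated correlation). BMI1 rose by 1.99 ± 0.10 and CBX8 by 1.75 ± 0.22, and PHC1 fell by 0.76 ± 0.06 (log2, SE).

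Tests chosen after the result was seen are those of exon length, of span alone, of the span slopes and of the length and GC offsets. The number of genes, 9268, had no equal among the 10 splits of the 6 libraries (1 split as large, the real one; highest other 0), and the same held for the 481 list members (1 split; highest other 0). For lists, 12 were called by the real split (1 split as large) and up to 10 by another. With 10 splits the share cannot fall under 0.05, so chance was not tested by it. Each of the other splits sets 2 libraries of 1 compound and 1 of the other against the rest, so it keeps part of the compound contrast, and the lists it calls do not show what differences unrelated to the compound would call.

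Among protein-coding genes past the threshold, most of those with the longest spans were lower and most of those with the shortest were higher. Spearman's rho of the log2 fold change was -0.41 with span and -0.30 with exon length. Loss of long mature transcripts through RNA fragmentation acts through mature length, for which exon length is a rough stand-in. The mean correlation with exon length within bands of equal span was -0.072, against -0.29 for span within bands of equal exon length. By a bound set after the values were seen, -0.072 would argue against fragmentation as the whole cause. Exon length joins the exons of all transcripts of a gene, so a weak correlation may also come from a poor measure. Fragmentation therefore stays open. Within bands of equal GC the correlation with span was -0.43, which argues against GC content. The groups' span slopes lay 0.0666 apart, more than the 0.0391 they ranged within a group, but 3 against 3 libraries are too few to exclude a difference between libraries unrelated to the compound, which cannot be told apart from it. An effect of the compound itself stays open, and no mechanism was tested.

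Ribosomal protein genes rose, and how far their short span accounts for it depends on how comparison genes are chosen. Their median of 0.29 lay above the central 95% of 10000 lists matched on span and expression (0.0794) and of lists matched also on exon length and GC (0.101), and just above that of lists matched on span alone (0.259, with 60 lists as high). Offsets for span, exon length and GC, which ignore expression, brought the median from 0.29 (quartiles 0.24 and 0.37) to 0.04 (-0.02 and 0.11) and ended the call. The offsets removed all 3 trends at once, so which of them ended it was not tested. Lists matched on span and expression had a median of 0.02. Span, whatever the expression, and a rise of this family therefore cannot be told apart here. The gap of 0.201 between the groups' per-library medians exceeded the range of 0.113 within a group, a comparison that 3 against 3 libraries leave open as well.

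Developmental Polycomb targets nearly silent in UNC2400 were tested only where UNC1999 was higher, which may raise the list's median. Matched genes had passed the same low-count filter, but were matched on mean expression over both groups. A gene of equal levels can pass at that mean, while a nearly silent target passes only where UNC1999 is higher. Matching therefore does not remove this selection. As a list, the tested targets were higher than tested genes of like mean expression and length, a difference that the filter partly sets. Their median over the 59 members with a length, 0.59, lay above the central 95% of 10000 lists matched on span and expression (0.306), on exon length and GC as well (0.33) and on span alone (0.234), and the list was still called with the offsets (adjusted p = 0.000221). With no low-count filter camera called the list too (adjusted p = 1.36e-06), though near-silent genes still have little room to fall. The list was not called with an estimated correlation (adjusted p = 0.463). Release of Polycomb repression by UNC1999 is a hypothesis for the rise of the tested targets, part of which the filter sets. Both groups also received DZNep and TSA, so levels in UNC2400 are not those of untreated cells. Direct release and later effects were not tested apart, since no chromatin data were analysed here. A difference between libraries that has nothing to do with the compound stays open with 3 libraries per group.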
